A study of Mus musculus with 15 samples.

How the data were processed

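The series holds 15 libraries of ATAC-seq (a transposase assay that marks accessible chromatin) from mouse liver, in 5 groups of 3. The groups were hepatocytes and biliary cells from untreated mice, and hepatocytes, reprogrammed hepatocytes and biliary cells from mice given diethoxycarbonyl-dihydrocollidine (DDC), a diet additive that injures the bile ducts. Per the labels, cells were sorted from liver without a step of growth in culture. The markers of the sort and the way reprogrammed cells were told from other hepatocytes are not given in the sources used here. No label says that replicates came from separate animals, so all p-values measure the spread between these libraries only, which may be technical. Within every group each pair of libraries differed by more than counting noise (chi-square per degree of freedom 2.34 to 8.2), so none was a copy of another.

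The deposited file gives 93217 regions of 179 to 48527 bp (median 706 bp) with a value per library. Per the submitters' processing notes, Bowtie2, SAMtools, MACS2 and bedtools were used with the mouse build mm10. Aligner settings, tool versions, the handling of duplicate reads and the way the regions of separate libraries were merged are not given in the sources used here. The authors call the values TPM, but the deposited values are RPM, reads in a region per 1e6 reads in all regions: every value up to 100 reads was a whole multiple of the library's smallest step (100% of values, tolerance 0.02), with no division by region length. The plan had taken the unit to be TPM, and the tests were kept because they use log2 of a library-scaled value in either case. For DDC reprogrammed library 1 the step of 1 read lies close to a power of 10, so its whole-number pattern is weaker evidence on its own. The scaling total includes 2 mitochondrial regions (bases 1 to 6581 and 10604 to 16299 of the mitochondrial genome), whose share differs strongly between groups.

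Regions were tied to genes with the given RefSeq table of the same build. That table has no strand, so transcription start sites were not used: a region went to the protein-coding gene whose body it touched, or else to the nearest within 50 kb. In this way 80398 regions (86.2%) were tied to 16587 of 21887 protein-coding genes. A gene's value is the summed accessibility of its regions, not its expression. Location classes used 1 kb around either gene end. Motifs were not analysed here, since no genome sequence was at hand.

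The design of the tests was fixed before the data were examined. The test was limma-trend on log2(RPM + 1) as deposited, with all 15 libraries in 1 fit and features of mean 1 or more, and Benjamini-Hochberg adjustment (adjusted p under 0.05) within each comparison. It covered 70540 regions and 16011 genes. Changes in log2 are given as estimate ± SE, and levels as mean ± SD over 3 libraries. Because 1 is added, the change of a gene with few reads is understated. After the mitochondrial share had been seen, 5 alternatives were added: RPM over nuclear reads only, called nuclear RPM or the nuclear scaling below (79075 regions, 16230 genes); edgeR quasi-likelihood tests on the recovered nuclear reads; nuclear reads thinned to equal depth, with only the compared groups in the fit; the same fit without thinning; and a fit without untreated hepatocytes. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, the data.table package (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

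A self-test drew nuclear reads with no change between groups while keeping each library's depth and mitochondrial share. On the deposited scale it called 15334 of 16004 genes between untreated biliary cells and hepatocytes, 14691 of 15996 between DDC and untreated hepatocytes, and 11824 of 15997 for the difference of the DDC effects. It called 0 of 16001 genes for biliary cells, 1 of 15993 between reprogrammed cells and DDC hepatocytes, and 0 of 16001 between reprogrammed and biliary cells. Under the nuclear scaling the numbers were, in the same order, 25 of 16217, 22 of 16215, 1 of 16191, 0 of 16203, 0 of 16201 and 0 of 16224. For the 3 comparisons that involve untreated hepatocytes, calls on the deposited scale alone therefore carry little weight. Calls made in the same direction under both scalings are given beside them. Such shared calls lie mostly in the direction that the deposited scale favours and are not independent support. Of 637 genes lower in DDC than in untreated hepatocytes under the nuclear scaling, 13 were lower under both. A further simulation changed 200 genes, split evenly between 2-fold and 4-fold changes. For reprogrammed cells against DDC hepatocytes 87% of the 4-fold genes were recovered as deposited and 90% under the nuclear scaling. Of the 2-fold genes 32% and 42% were recovered. For reprogrammed against biliary cells the deposited scale recovered 8% at 2-fold and 97% at 4-fold. The nuclear scaling recovered 57% and 89% there, and edgeR 81% and 100%.

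Gene lists written before the data were examined held 459 entries, of which 455 matched a gene and 421 had a region. An entry that is itself the symbol of a non-coding gene was not matched through a synonym of another gene; H19 had first been matched to Nckap1, and this was corrected after results had been seen. The 25 lists were hepatocyte function, hepatocyte transcription factors, biliary, Notch, Hippo-YAP targets, AP-1 and immediate early genes, TGF-beta and epithelial-mesenchymal transition, fetal liver progenitor, Wnt targets, cell cycle, inflammation and chemokines, interferon response, xenobiotic response, NRF2 targets, heme synthesis, bile acid handling, lipid and glucose metabolism, macrophage and Kupffer, lymphocyte, neutrophil, endothelial, stellate and mesenchymal, mesothelial, erythroid, and neuronal control. The 24 with 5 or more measured members were tested with camera at an inter-gene correlation of 0.01, adjusted over 144 tests, with an estimated correlation beside it. In a self-test that drew each gene independently, a planted list of 30 genes reached adjusted p = 7.41e-57, and 0.0114 with an estimated correlation. Of the random lists 0 were called. Members of the real lists were correlated (estimated correlation 0.71 for hepatocyte function), so this self-test cannot give their rate of false calls.

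Genes named in the text came from a fixed rule: the 10 largest changes per direction among called genes with groups that did not overlap, a summed level of 10 or more, and a symbol that is not a clone name; up to 4 members of each list with the smallest adjusted p; and Alb, Hnf4a, Krt19, Sox9, Epcam and Spp1 in every comparison. Some genes with hardly any reads in a compared group, and some that lost their call in many fits with a library left out, are not named.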

Results

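Mitochondrial reads set the cell types apart before any gene was compared. They made up 76.6 ± 11.72% of reads in regions in untreated hepatocytes and 34.1 ± 7.24% in DDC hepatocytes (mean ± SD, n = 3 each). In reprogrammed cells the share was 9.23 ± 5.13%, in DDC biliary cells 9.87 ± 2.65% and in untreated biliary cells 18.63 ± 4.35%. Nuclear reads per library ranged from 201705 to 605309 in untreated hepatocytes and from 5151190 to 10395918 in DDC biliary cells. Regions without a read accordingly made up 52.13 ± 10.22% in untreated hepatocytes and 2.83 ± 0.93% in DDC biliary cells. A region's deposited value falls as the mitochondrial share rises, so the counts of calls of every comparison are given under both scalings.

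**Figure D1:**
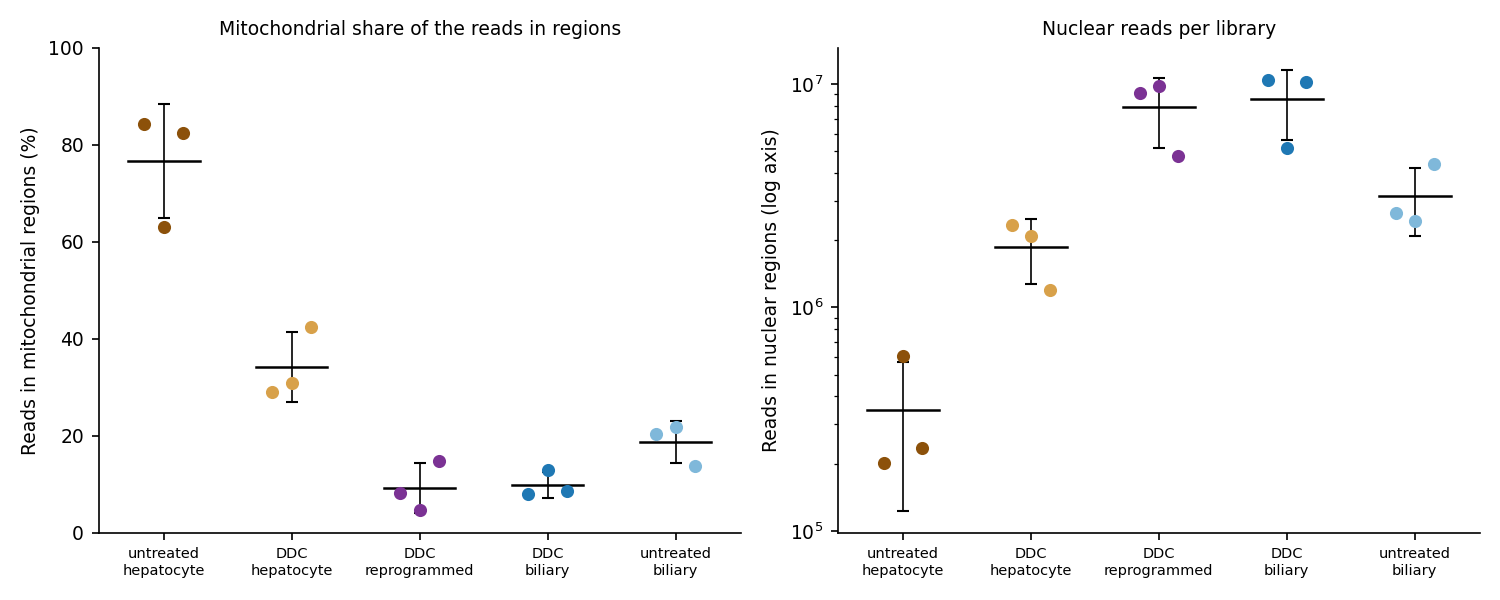
Mitochondrial share and nuclear reads of each library. Untreated hepatocytes had a mitochondrial share of 76.6 ± 11.72% against 9.23 ± 5.13% in reprogrammed cells (mean ± SD, n = 3).

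Untreated biliary cells differed from untreated hepatocytes at genes of both lineages. Spp1, which encodes the secreted bile duct protein osteopontin, rose by 5.25 ± 0.32 in biliary cells as deposited (n = 3 per group, adjusted p = 1.36e-09) and by 3.54 ± 0.26 under the nuclear scaling. Krt19, the keratin of bile duct cells, rose by 4.0 ± 0.41 (nuclear 2.36 ± 0.49), and Epcam, an adhesion molecule of biliary epithelium, by 3.53 ± 0.26 (nuclear 1.75 ± 0.19). Tdo2, which starts the breakdown of tryptophan in hepatocytes, fell by 2.55 ± 0.64 (nuclear −4.46 ± 0.67), and Igfbp1, a hepatic binding protein of growth factors, fell by 2.22 ± 0.53 (nuclear −4.13 ± 0.50). Hpx, the plasma heme carrier hemopexin, Pck1, an enzyme of glucose production, and F9, coagulation factor IX, also fell (−2.02 ± 0.49, −2.06 ± 0.52 and −1.86 ± 0.49). Alb, the gene of albumin, did not pass as deposited (−0.84 ± 0.43, adjusted p = 0.074) but fell under the nuclear scaling (−2.75 ± 0.37, adjusted p = 7.36e-05). The same held for Hnf4a, the main transcription factor of hepatocytes (−0.45 ± 0.42, adjusted p = 0.305; nuclear −2.35 ± 0.33, adjusted p = 9.83e-05), which turned to 1.58 with regions within 1 kb of a gene end. The leading region lay in Spp1 (chromosome 5, 104436440 to 104444729) and rose by 6.59 ± 0.41 (adjusted p = 9.68e-11).

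Of the biliary list, 34 of 34 members rose as deposited (34 adjusted over the list alone) and 23 rose under both scalings (camera adjusted p = 1.51e-06, adjusted p = 0.556 with an estimated correlation). Grhl2, a transcription factor of epithelia, rose by 4.13 ± 0.27 (nuclear 2.40 ± 0.32), and Cdh1, which encodes E-cadherin, by 3.45 ± 0.25 (nuclear 1.59 ± 0.16). Among Hippo-YAP targets 22 of 22 rose (22 adjusted over the list alone), 16 under both scalings (adjusted p = 0.000113, adjusted p = 0.556 with an estimated correlation). Ankrd1, a classic target of YAP, led all named genes (5.83 ± 0.52, nuclear 4.91 ± 0.85), and Ptpn14 rose by 4.48 ± 0.27 (nuclear 2.66 ± 0.28). All 17 Notch members rose, 8 under both scalings (adjusted p = 0.00691, adjusted p = 0.933 with an estimated correlation), among them the Notch target Hes1 (3.46 ± 0.27, nuclear 1.58 ± 0.12). As deposited 13743 of 16011 genes rose, so a high count alone does not set a list apart. The neuronal control rose in 11 of 12 (camera adjusted p = 0.844). Under the nuclear scaling 4 of its members rose and 3 fell, with a median of 0.79. For Notch 8 rose and 0 fell there, with a median of 0.59. All 17 AP-1 members rose, 12 under both (adjusted p = 0.000742, adjusted p = 0.93 with an estimated correlation), with Atf3 at 3.54 ± 0.28 and Fosb at 3.69 ± 0.32. Of the hepatocyte function list 1 member rose, 14 fell and 22 did not pass (1 and 11 adjusted over the list alone), and 14 fell under both scalings (adjusted p = 2.53e-53, adjusted p = 0.398 with an estimated correlation). All 37 fell under the nuclear scaling.

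Bile acid handling had 7 members that rose and 3 that fell of 20 (5 and 1 adjusted over the list alone); its median was 0, its mean 0.17 and its test pointed down (adjusted p = 3e-12, adjusted p = 0.46 with an estimated correlation). Of the 20 members 16 fell under the nuclear scaling. Xenobiotic response (6 of 18 rose, 0 under both; nuclear 7 fell) and lipid and glucose metabolism (15 rose and 1 fell of 22; nuclear 1 and 11) also tested as lower than other genes. Their adjusted p was 1.61e-07 and 0.00334, which became adjusted p = 0.46 and adjusted p = 0.945 with an estimated correlation. Hepatocyte transcription factors showed the shift most plainly: 16 of 20 rose as deposited and 10 fell under the nuclear scaling, with 0 shared. The lymphocyte list (adjusted p = 0.0102, adjusted p = 0.512 with an estimated correlation) and the endothelial list (adjusted p = 0.0388, adjusted p = 0.619 with an estimated correlation) lay below other genes as deposited. Neither passed under the nuclear scaling (adjusted p = 0.885 and 0.326). Without untreated hepatocyte library 1 the endothelial list gave 0.0574, without untreated biliary library 2 it gave 0.0511 and without library 3 it gave 0.0887. Lipid and glucose metabolism gave 0.16 without untreated hepatocyte library 2.

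In total 13902 of 16011 genes passed as deposited (13743 higher, 159 lower, 98.9% higher) against 6343 under the nuclear scaling (4138 and 2205, 65.2% higher) and 4773 with edgeR (48.4% higher). Genes that passed in the same direction under both scalings numbered 4118 higher and 159 lower, and 930 genes passed in opposite directions. For regions the numbers were 40969 as deposited (95.1% higher), 26102 under the nuclear scaling (67.0% higher) and 16769 higher and 1982 lower under both, with 325 in opposite directions. The median of all genes was 1.91 as deposited and 0.32 under the nuclear scaling, so a deposited change is to be read relative to 1.91. In a fit of only the compared groups on nuclear values, thinning to 201705 reads per library took gene calls from 2750 to 829. Region calls went from 12571 to 1817. The calls of Sox9, Krt19 and Lfng were among those that ended. Sox9 went from 1.27 to 0.63 (adjusted p = 0.00699 and 0.232), while Krt19 (2.36 and 2.87; adjusted p = 0.042 and 0.0685) and the Notch modifier Lfng (1.62 and 1.55; adjusted p = 0.0234 and 0.141) kept folds of about the same size. Alb passed without untreated hepatocyte library 3 (−1.27, adjusted p = 0.0157) or untreated biliary library 1 (−1.16, adjusted p = 0.0301), and Hnf4a without untreated hepatocyte library 1 (−0.95, adjusted p = 0.034).

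**Figure D2:**
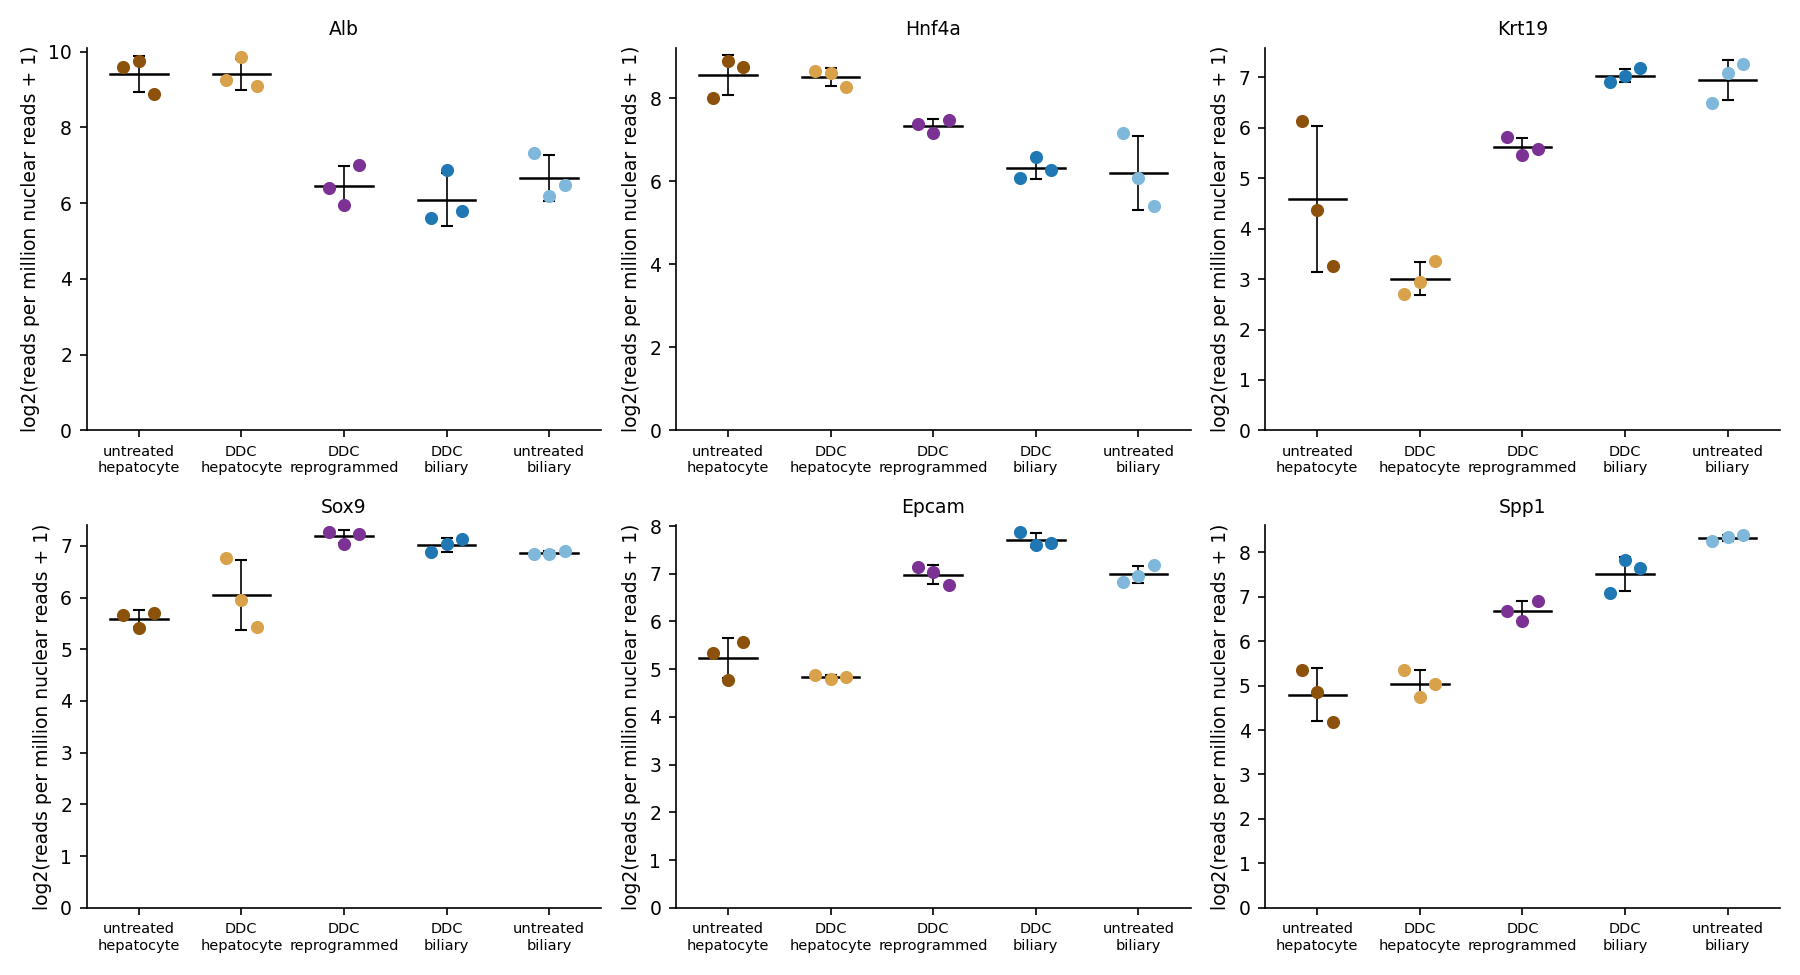
Accessibility of Alb, Hnf4a, Krt19, Sox9, Epcam and Spp1 in nuclear RPM (log2) in each library. Alb measured 701 ± 208 in untreated hepatocytes and 90.6 ± 33.5 in reprogrammed cells, and Epcam 37.6 ± 10.3 and 126 ± 17.5 (mean ± SD, n = 3).

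In the fit of all libraries, DDC hepatocytes had higher values of Krt18, Krt8, Fosb and Scd1 under both scalings. Alb and Hnf4a stayed near their untreated level under the nuclear scaling. With only the compared groups in the fit, nuclear values called 1 gene, which fell, and thinned reads called 0. None of the genes named here was called there. Krt18 and Krt8, keratins that hepatocytes raise on injury, rose by 3.21 ± 0.36 and 2.73 ± 0.31 as deposited (n = 3 per group; adjusted p = 2.65e-06 for each) and by 1.71 ± 0.27 and 1.16 ± 0.23 under the nuclear scaling. Fosb, an AP-1 subunit, rose by 2.80 ± 0.32 (nuclear 1.25 ± 0.20), and Scd1, which desaturates fatty acids, by 2.96 ± 0.30 (nuclear 1.43 ± 0.19, adjusted p = 0.000531). Ccl2, the chemokine that draws monocytes, rose by 2.73 ± 0.29 (nuclear 1.24 ± 0.31, adjusted p = 0.0182). Prss22, a serine protease, rose by 4.08 ± 0.41 (nuclear 2.89 ± 0.32, adjusted p = 0.000167), and Vmn2r93, a vomeronasal receptor gene, fell by 2.40 ± 0.47 (nuclear −4.25 ± 0.54), on 46 reads in untreated and 10 in DDC hepatocytes. Alb rose by 1.58 ± 0.43 as deposited but stood at −0.01 ± 0.37 under the nuclear scaling (adjusted p = 0.99), and Hnf4a turned likewise from 1.55 ± 0.42 to −0.04 ± 0.33. Epcam turned from 1.09 ± 0.26 to −0.40 ± 0.19 (adjusted p = 0.17). Sox9, a biliary transcription factor, rose by 1.96 ± 0.33 as deposited and did not pass under the nuclear scaling (0.46 ± 0.24, adjusted p = 0.199), nor did Spp1 (1.68 ± 0.32; nuclear 0.25 ± 0.26, adjusted p = 0.532; −0.39 with thinned reads). Krt19 did not pass as deposited (−0.16 ± 0.41, adjusted p = 0.713) and fell under the nuclear scaling (−1.58 ± 0.49, adjusted p = 0.0425); without untreated hepatocyte library 3 it fell as deposited too (−0.83, adjusted p = 0.0187). Krt19 had 14, 12 and 2 reads in the untreated hepatocyte libraries, and with only the compared groups in the fit it did not pass on nuclear values (−1.59, adjusted p = 0.386) or thinned reads (−0.25, adjusted p = 0.953).

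AP-1 was the list that stood above other genes under both scalings. Of its members 16 of 17 rose (16 adjusted over the list alone), 8 under both scalings, with a median 0.55 above that of all genes (camera adjusted p = 0.000938, adjusted p = 0.93 with an estimated correlation). Under the nuclear scaling adjusted p = 0.00079 (adjusted p = 0.132 with an estimated correlation). Atf3, a stress-induced transcription factor, rose by 2.35 ± 0.28 (nuclear 0.76 ± 0.14), Mafk by 2.53 ± 0.30 (nuclear 1.0 ± 0.15) and Fosl2 by 2.13 ± 0.26 (nuclear 0.58 ± 0.13). Among lipid and glucose genes 20 of 22 rose, 3 under both scalings, among them Fasn, the fatty acid synthase (2.48 ± 0.30, nuclear 0.90 ± 0.24). Xenobiotic response had 15 of 18 that rose and 2 under both, with Cyp3a13 at 3.06 ± 0.35 (nuclear 1.92 ± 0.36). The macrophage marker Cd68 rose by 2.42 ± 0.28 (nuclear 0.95 ± 0.17), and of its list 6 of 7 rose, 1 under both. Among all genes 13539 of 16011 rose as deposited and 1553 under both scalings. The lipid and glucose, xenobiotic and macrophage lists did not pass (camera adjusted p = 0.307, 0.54 and 0.982). Nor did they pass under the nuclear scaling (camera adjusted p = 0.992, 0.499 and 0.483). Of the hepatocyte function list 19 of 37 rose as deposited (17 adjusted over the list alone), 0 under both and 5 fell under the nuclear scaling; its median was 1.19 while its test pointed down (adjusted p = 3.17e-05, adjusted p = 0.945 with an estimated correlation). The biliary list had 26 of 34 that rose as deposited, and 5 rose and 5 fell under the nuclear scaling. Trf, the gene of transferrin, rose by 2.65 ± 0.41 (nuclear 1.06 ± 0.34, adjusted p = 0.0522).

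As deposited 13553 genes passed (13539 higher, 14 lower, 99.9% higher), against 2200 under the nuclear scaling (1563 and 637, 71.0% higher) and 814 with edgeR (57.2% higher). Those in the same direction under both scalings numbered 1553 higher and 13 lower, and 299 passed in opposite directions. Region calls were 33777 as deposited (99.4% higher) and 9598 under the nuclear scaling (81.9% higher), with 7356 higher and 178 lower under both and 107 in opposite directions. The median of all genes moved from 1.54 to 0.21, and deposited changes are to be read relative to 1.54. With only the compared groups in the fit, nuclear values gave 1 gene (2214 at unadjusted p under 0.05), none of those named here, and 0 regions (9519). The same fit thinned to 201705 reads gave 0 genes (1590) and 0 regions (4733). The lymphocyte list lay below other genes (adjusted p = 0.000158, adjusted p = 0.46 with an estimated correlation), as did the neuronal control (adjusted p = 0.0354, adjusted p = 0.619 with an estimated correlation), which gave 0.0594 without untreated hepatocyte library 2 and 0.111 without DDC hepatocyte library 1. Neither list passed under the nuclear scaling (adjusted p = 0.419 and 0.27).

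In biliary cells DDC raised members of the inflammation and chemokine list, Ccl2 among them. Ccl2 rose by 2.94 ± 0.29 (n = 3 per group, adjusted p = 2.45e-05; nuclear 2.81 ± 0.31), from 26.1 ± 3.47 to 192 ± 47.2 nuclear RPM. Il23a, a subunit of the cytokine IL-23, rose by 3.23 ± 0.36 (adjusted p = 7.41e-05; nuclear 3.14 ± 0.41), and Csf2, the growth factor of granulocytes and macrophages, by 3.25 ± 0.46. Pglyrp4, which binds bacterial peptidoglycan, rose most among the genes named (3.79 ± 0.43, adjusted p = 7.41e-05), followed by Il1f6, a cytokine of epithelia (3.49 ± 0.49), and Tff1, a peptide that protects mucosa (3.38 ± 0.49). Msln, which encodes mesothelin, rose by 3.13 ± 0.39 (adjusted p = 0.000175). Frmd7 (−1.98 ± 0.38, adjusted p = 0.0055) and the amylase gene Amy1 (−1.60 ± 0.36, adjusted p = 0.0157) fell. The leading region lay inside St3gal1, a sialyltransferase gene (chromosome 15, 67138353 to 67139618), and rose by 4.74 ± 0.53 (adjusted p = 1.5e-05).

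Of inflammation and chemokine genes 6 of 19 rose and 0 fell (9 rose adjusted over the list alone), 5 of them under both scalings, with a median of 0.87 (camera adjusted p = 2.89e-07, adjusted p = 0.46 with an estimated correlation). Vcam1, an adhesion molecule for leukocytes, rose by 1.84 ± 0.36 (adjusted p = 0.00622). The macrophage list had 2 of 7 that rose (3 adjusted over the list alone; 0 under the nuclear scaling; adjusted p = 0.0032, adjusted p = 0.46 with an estimated correlation). The endothelial list had 1 of 15 that rose, Stab1, a scavenger receptor of sinusoidal endothelium (1.88 ± 0.34; 7 adjusted over the list alone; adjusted p = 0.0181, adjusted p = 0.556 with an estimated correlation). TGF-beta and epithelial-mesenchymal genes had 2 of 19 that rose (6 adjusted over the list alone; adjusted p = 0.0892), among them Ltbp2, which binds elastic fibres (1.89 ± 0.28). The biliary list lay above other genes (adjusted p = 0.00503, adjusted p = 0.933 with an estimated correlation), with 1 of 34 that rose, Cldn4, a tight junction protein (1.99 ± 0.50, adjusted p = 0.0324; nuclear adjusted p = 0.114), and 9 adjusted over the list alone. In the hepatocyte function list limma called 0 of 37 (2 higher and 4 lower at unadjusted p under 0.05; 7 fell with edgeR), and the list lay below other genes (median −0.25, adjusted p = 0.00235, adjusted p = 0.945 with an estimated correlation). Of AP-1 members limma called 0 of 17 as deposited (3 higher and 1 lower at unadjusted p under 0.05, 2 and 1 adjusted over the list alone). Under the nuclear scaling 1 rose and 2 fell, and with edgeR 3 rose and 2 fell. Itgam, a marker of neutrophils and other myeloid cells, rose by 1.66 ± 0.41 (adjusted p = 0.031; nuclear adjusted p = 0.222).

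None of the 6 genes followed throughout passed in the fit of all libraries: Epcam was at 0.86 ± 0.26 (adjusted p = 0.0795; edgeR 0.000976), Spp1 at −0.67 ± 0.32 (0.382; edgeR 0.00345), Sox9 at 0.30 ± 0.33 (0.838), Krt19 at 0.23 ± 0.41 (0.931), Alb at −0.43 ± 0.43 (0.814) and Hnf4a at 0.25 ± 0.42 (0.924). With only the compared groups in a nuclear fit Epcam (0.72, adjusted p = 0.000455) and Spp1 (−0.82, adjusted p = 0.00111) passed. In total 498 genes passed (468 higher, 30 lower, 94.0% higher), against 543 under the nuclear scaling (364 and 179, 67.0% higher) and 2603 with edgeR (66.1% higher); 244 higher and 21 lower passed under both scalings. For regions the counts were 8721 (91.6% higher), 2741 (84.3% higher) and 10467 with edgeR (74.3% higher). With only the compared groups in the deposited fit 4160 genes and 17311 regions passed. The median of all genes was 0.12 as deposited and −0.02 under the nuclear scaling.

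The number of genes called in biliary cells depended on each library. Without DDC biliary library 1, 2 or 3 it was 101, 314 or 112, and without untreated biliary library 1, 2 or 3 it was 284, 168 or 153. Region calls became 4431 without DDC biliary library 1, 4754 without its library 3 and 5659 without untreated biliary library 3. Cldn4 (adjusted p = 0.0607 to 0.164), Lfng (1.14 ± 0.28; 0.0593 to 0.192) and the Notch ligand Dll1 (0.98 ± 0.26; 0.0773 to 0.252) lost their call with any library left out, at folds of 1.86 to 2.12, 1.07 to 1.24 and 0.89 to 1.07. Vcam1 lost it without DDC biliary library 3 (1.57, adjusted p = 0.0852) or untreated biliary library 2 (1.51, adjusted p = 0.0638), and Frmd7 without DDC biliary library 3 (−1.82, adjusted p = 0.0591). Amy1 (−1.54 to −1.47) lost it without DDC biliary libraries 1 (0.129) and 3 (0.104) and untreated biliary libraries 1 (0.0744) and 3 (0.0923), and Itgam (1.45 to 1.62) without DDC biliary libraries 1 (0.213) and 3 (0.185) and untreated biliary libraries 2 (0.12) and 3 (0.17). With all biliary libraries but no untreated hepatocytes in the fit these 7 genes passed (adjusted p = 2.8e-05 to 0.00257). The biliary list gave 0.0513 without untreated biliary library 1, hepatocyte function 0.122 without DDC biliary library 1 and 0.972 without untreated biliary library 1, and endothelial 0.0926 without untreated biliary library 3.

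Reprogrammed cells had lost accessibility at hepatocyte genes and gained it at biliary genes compared with the hepatocytes of the same treatment. Alb fell by 2.48 ± 0.43 (n = 3 per group, adjusted p = 0.000441; nuclear −2.94 ± 0.37), from 693 ± 209 to 90.6 ± 33.5 nuclear RPM. Cyp2e1, which oxidizes ethanol, fell by 2.69 ± 0.58 (adjusted p = 0.00222). Krt19 rose by 2.99 ± 0.41 (adjusted p = 5.64e-05; nuclear 2.61 ± 0.49), Epcam by 2.58 ± 0.26 (adjusted p = 5.75e-06; nuclear 2.14 ± 0.19), Spp1 by 2.07 ± 0.32 (adjusted p = 0.000167) and Sox9 by 1.59 ± 0.33 (adjusted p = 0.00181). Hnf4a did not pass as deposited (−0.71 ± 0.42, adjusted p = 0.2) but fell under the nuclear scaling (−1.18 ± 0.33, adjusted p = 0.0259; edgeR 0.000357), to 162 ± 18.3 nuclear RPM from 370 ± 52.5. Lce1m, a gene of the late cornified envelope of skin, rose most (4.37 ± 0.51, adjusted p = 1.28e-05), and Amotl1, an angiomotin that binds YAP, rose by 3.61 ± 0.31 (adjusted p = 1.21e-06).

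Of the hepatocyte function list 24 of 37 fell, 0 rose and 13 did not pass (31 fell adjusted over the list alone), all 24 under both scalings (median −1.62; camera adjusted p = 7.7e-39, adjusted p = 0.46 with an estimated correlation). Arg1, of the urea cycle, fell by 2.19 ± 0.46, and Slco1b2, an organic anion transporter, by 2.15 ± 0.40. Of the biliary list 23 of 34 rose and 0 fell (25 rose adjusted over the list alone), 18 under both scalings (median 1.44; adjusted p = 2.25e-09, adjusted p = 0.46 with an estimated correlation). Grhl2 rose by 2.54 ± 0.27 and Cd24a, a surface protein of biliary progenitors, by 2.52 ± 0.30. Hippo-YAP targets had 16 of 22 that rose (17 adjusted over the list alone), 9 under both scalings, with a median of 1.32 (adjusted p = 3.59e-07, adjusted p = 0.46 with an estimated correlation). With nuclear scaling the list passed (adjusted p = 1.01e-06), also with an estimated correlation (adjusted p = 0.0391). Ccn2, a matrix protein induced by YAP, rose by 2.89 ± 0.30 (adjusted p = 5.75e-06). Of Notch genes 11 of 17 rose (12 adjusted over the list alone), 7 under both scalings (adjusted p = 0.00113, adjusted p = 0.878 with an estimated correlation), led by Lfng (3.28 ± 0.28, adjusted p = 1.21e-06) and the ligand Jag2 (2.82 ± 0.39, adjusted p = 5.98e-05).

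Metabolic lists lay below other genes, although most of their members did not pass as deposited. Bile acid handling had 4 of 20 that fell (4 adjusted over the list alone; nuclear 9), among them Cyp7a1, the first enzyme of bile acid synthesis (−2.07 ± 0.45, adjusted p = 0.00266); its list test gave adjusted p = 4.56e-10 (adjusted p = 0.46 with an estimated correlation). Lipid and glucose metabolism had 4 of 22 that fell (4 adjusted over the list alone; nuclear 12; adjusted p = 4.57e-09, adjusted p = 0.556 with an estimated correlation), with Pck1 at −2.33 ± 0.52. Xenobiotic response had 2 that rose and 2 that fell of 18 (the same counts adjusted over the list alone). Under the nuclear scaling 1 rose and 5 fell, and with edgeR 1 rose and 13 fell. Its list test gave adjusted p = 6.31e-07 (adjusted p = 0.46 with an estimated correlation). Its member Nr1i3, the xenobiotic receptor CAR, was at −1.96 ± 0.57 (adjusted p = 0.0174). Nr1i3 lost its call without DDC hepatocyte library 2 (−1.58, adjusted p = 0.089) or reprogrammed libraries 1 (−1.87, adjusted p = 0.0673) and 2 (−1.85, adjusted p = 0.0709). Hepatocyte transcription factors had 1 that rose and 1 that fell of 20 (0 and 0 adjusted over the list alone); the median was 0.03, the mean −0.10 and the test pointed down (adjusted p = 0.0032, adjusted p = 0.945 with an estimated correlation), and 8 fell under the nuclear scaling.

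Lists of injury and of other cell types had members that rose, macrophages apart, and none of those tested passed with camera as deposited. Inflammation and chemokine genes had 10 that rose and 1 that fell of 19 (12 and 2 adjusted over the list alone; adjusted p = 0.101; nuclear adjusted p = 0.0462, adjusted p = 0.317 with an estimated correlation), among them Cxcl5, which draws neutrophils (2.5 ± 0.42), and Ccl2 (1.48 ± 0.29, adjusted p = 0.00116). AP-1 genes had 8 of 17 that rose (11 adjusted over the list alone; adjusted p = 0.1), and TGF-beta and epithelial-mesenchymal genes 9 of 19 (10 adjusted over the list alone; adjusted p = 0.111). Itgb6, an integrin that activates TGF-beta, rose by 2.93 ± 0.30 (adjusted p = 5.75e-06). Among macrophage markers limma called 0 of 7 (0 at unadjusted p under 0.05; edgeR 0; list adjusted p = 0.593): Cd68 was at 0.31 ± 0.28 and turned to −0.15 ± 0.17 under the nuclear scaling, and Csf1r at 0.43 ± 0.34 and −0.02 ± 0.33. Of the neutrophil list 4 members were measured, too few for a list test; Csf3r, the receptor for the granulocyte growth factor, rose by 2.23 ± 0.39 (adjusted p = 0.000403). Stellate and mesenchymal genes had 7 of 15 that rose (7 adjusted over the list alone, 3 under both scalings; adjusted p = 0.0968), among them Rgs5, of pericytes (2.66 ± 0.29), and Col1a1, a collagen chain (1.99 ± 0.34). Mesothelial genes had 3 of 5 that rose (4 adjusted over the list alone; adjusted p = 0.0933), with Muc16 at 3.38 ± 0.43 (adjusted p = 2.54e-05).

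As deposited 3952 genes passed (3531 higher, 421 lower, 89.3% higher), against 2318 under the nuclear scaling (1272 and 1046, 54.9% higher) and 4900 with edgeR (49.3% higher). Both scalings together gave 1270 higher and 354 lower. Region calls were 24657 (75.4% higher), 11232 (57.3% higher) and 23463 (52.8% higher), and 6283 higher and 3953 lower under both scalings. The median of all genes was 0.55 as deposited and 0.12 under the nuclear scaling, so a deposited change is to be read relative to 0.55. Gene calls became 2611 and 2514 without DDC hepatocyte libraries 2 and 3, and 2022 and 2083 without reprogrammed libraries 1 and 2; region calls became 15481 without reprogrammed library 1. Leading regions were 1 at 25453 bp from Aldh1a2, a retinoic acid synthase gene (chromosome 9, 71320872 to 71322519; 4.80 ± 0.47, adjusted p = 9.65e-07), and 1 beside the cytochrome gene Cyp2d9 (chromosome 15, 82456088 to 82459679; −3.23 ± 0.72, adjusted p = 0.00167).

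**Figure D3:**
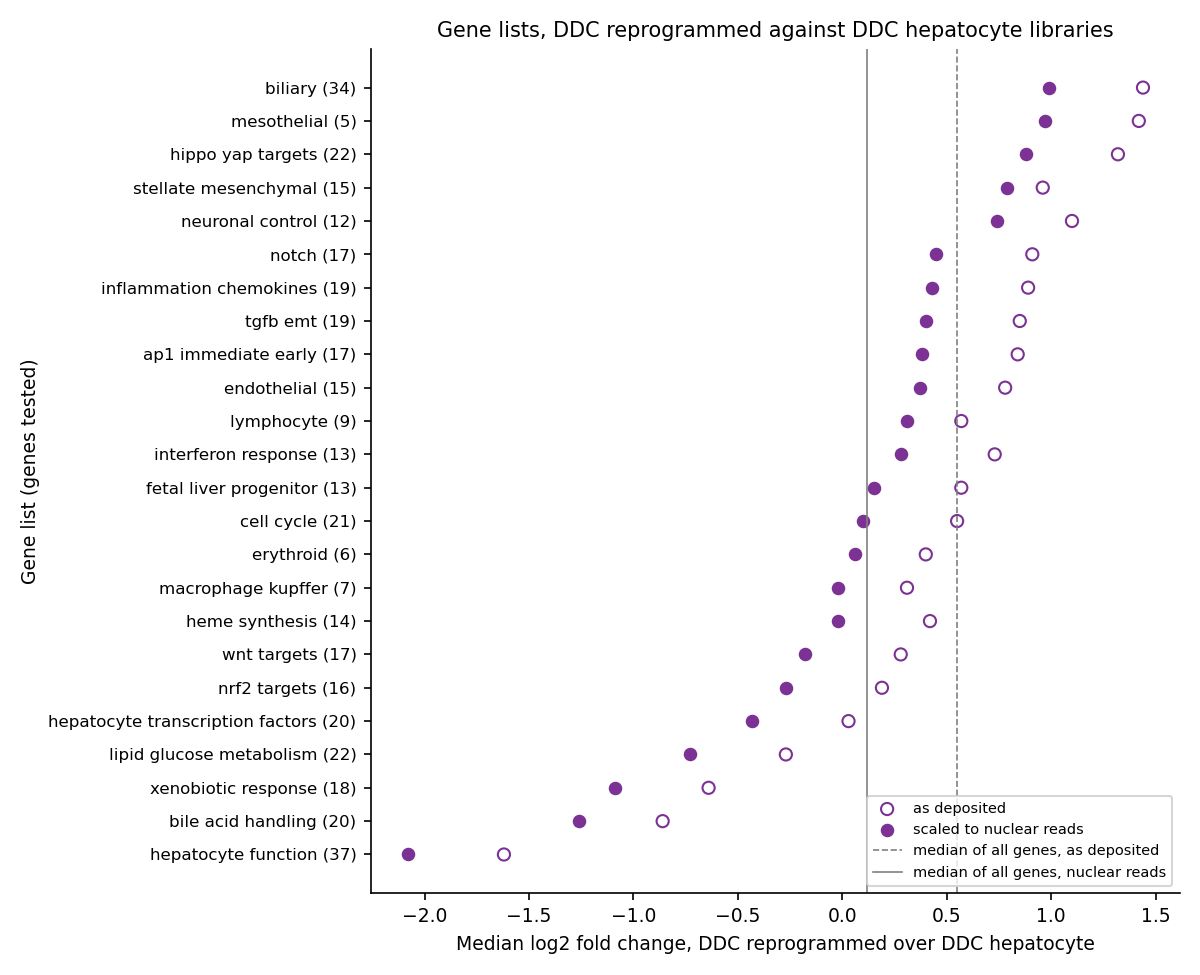
Median log2 change of each gene list between reprogrammed cells and DDC hepatocytes under both scalings. Hepatocyte function lay at −1.62 as deposited and −2.08 under the nuclear scaling and biliary at 1.44 and 0.99; hepatocyte transcription factors flipped from 0.03 to −0.43, heme synthesis from 0.42 to −0.02, Wnt targets from 0.28 to −0.18, NRF2 targets from 0.19 to −0.27 and macrophage from 0.31 to −0.02.

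Between reprogrammed cells and DDC biliary cells 4 genes passed in the deposited fit of all 15 libraries. Leaving untreated hepatocytes out of that fit gave 271 genes and 1968 regions, and only the compared groups gave 1084 genes and 6217 regions, so the count depended on the fit. Nox4, an oxidase that makes hydrogen peroxide, was higher in reprogrammed cells by 2.38 ± 0.39, with 18.8 ± 0.723 against 2.88 ± 1.17 nuclear RPM (n = 3 per group) and 29.9 ± 14 in DDC hepatocytes. Fxyd1, a regulator of the sodium pump, was higher by 2.15 ± 0.38 (69.3 ± 3.82 against 15.4 ± 5.07; DDC hepatocytes 89.7 ± 11.1). Lrfn4, a synaptic adhesion gene, was lower by −2.48 ± 0.43 (3.63 ± 2.56 against 23.3 ± 4.52). All had adjusted p = 0.0496, as had Fads2b, a fatty acid desaturase gene (chromosome 2, 85484092 to 85518935; −1.94 ± 0.33), which lies outside the naming rule and was chosen after its values were seen. Under the nuclear scaling Fxyd1 passed (adjusted p = 0.012), while Nox4 (0.0612), Lrfn4 (0.287) and Fads2b (0.105) did not. With edgeR all 4 passed, at 3.59e-06, 4.24e-05, 0.000131 and 0.000987 in that order.

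The lineage lists differed as groups although limma called none of their members in the deposited fit of all libraries. In the biliary list limma called 0 of 34 (10 lower at unadjusted p under 0.05; 4 lower adjusted over the list alone; 13 with edgeR), and the list was lower in reprogrammed cells (median −0.42; camera adjusted p = 3.48e-15, adjusted p = 0.46 with an estimated correlation). With nuclear scaling 1 member was lower and the list passed (adjusted p = 1.66e-17), also with an estimated correlation (adjusted p = 0.0391). In the hepatocyte function list it called 0 of 37 (6 higher at unadjusted p under 0.05; 4 with edgeR), and the list was higher (median 0.54; adjusted p = 4.57e-09, adjusted p = 0.847 with an estimated correlation). Bile acid handling was higher too (0 of 20 called, 3 at unadjusted p under 0.05, 2 with edgeR; median 0.56, adjusted p = 0.000742, adjusted p = 0.93 with an estimated correlation). Krt19 stood at −1.41 ± 0.41 (adjusted p = 0.391; edgeR 0.000131), Epcam at −0.72 ± 0.26 (0.731; edgeR 0.00326), Spp1 at −0.83 ± 0.32 (0.828; edgeR 0.00312) and Hnf4a at 1.04 ± 0.42 (0.856; edgeR 0.0278). Without untreated hepatocytes in the fit these 4 passed (Krt19 adjusted p = 0.00151, Epcam 0.0363, Spp1 0.0201 and Hnf4a 0.0466). Sox9 (0.17 ± 0.33) and Alb (0.38 ± 0.43) passed with neither tool.

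In all 4 genes (2 higher, 2 lower; 722 at unadjusted p under 0.05) and 440 regions (47 higher, 393 lower, 10.7% higher) passed as deposited. The nuclear scaling gave 4 genes (3 and 1) and 0 regions with limma, with 4309 regions at unadjusted p under 0.05. edgeR called 478 genes (169 higher, 309 lower) and 2113 regions (642 and 1471, 30.4% higher). In the self-test of this comparison, with 200 changed genes among 16001, 8% of those changed 2-fold were recovered as deposited. On that scale small differences would thus mostly be missed. The nuclear scaling recovered 57% of them and edgeR 81%, where edgeR also called 0.139% of unchanged genes. Leaving out any 1 of the 6 libraries left 0 genes, and regions numbered 0, 0 and 53 without reprogrammed libraries 1, 2 and 3 and 0, 1 and 0 without DDC biliary libraries 1, 2 and 3. Nox4 was then at 2.11 to 2.53 (adjusted p = 0.169 to 0.423), Fxyd1 at 1.9 to 2.33 (0.204 to 0.528) and Lrfn4 at −2.86 to −2.18 (0.095 to 0.719), so the calls ended while the folds stayed. Without untreated hepatocytes in the fit they passed (Nox4 adjusted p = 0.000437, Fxyd1 4.68e-05 and Lrfn4 0.00117).

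The last comparison subtracted the DDC change in hepatocytes from that in biliary cells, so that a negative value marks a lower change in biliary cells. Atf3 differed by −3.25 ± 0.39 (n = 3 per group, adjusted p = 0.000493; nuclear −1.81 ± 0.20). Nuclear values of Atf3 rose by 0.76 ± 0.14 in hepatocytes and fell by 1.05 ± 0.14 in biliary cells (adjusted p = 0.00224), where it did not pass as deposited (−0.90 ± 0.28, adjusted p = 0.0825). Fosb differed by −2.95 ± 0.45 (nuclear −1.55 ± 0.28). Scd1 differed by −3.19 ± 0.42 (nuclear −1.80 ± 0.27), Ccn1, a matrix protein induced by YAP, by −2.71 ± 0.38 (nuclear −1.27 ± 0.23) and Hes1 by −2.25 ± 0.38 (nuclear −0.83 ± 0.16). Il23a differed in the other direction (2.94 ± 0.50, adjusted p = 0.000904; nuclear 4.20 ± 0.57), as did Lce1m (3.68 ± 0.72; nuclear 4.46 ± 1.08). Alb (−2.01 ± 0.61, adjusted p = 0.0103), Sox9 (−1.66 ± 0.47) and Spp1 (−2.34 ± 0.46) passed as deposited but not under the nuclear scaling (−0.56, −0.31 and −1.07; adjusted p = 0.58, 0.652 and 0.126). Epcam turned from −0.23 ± 0.37 (adjusted p = 0.587) to 1.12 ± 0.27 (adjusted p = 0.0425) and Hnf4a from −1.30 ± 0.59 (adjusted p = 0.0583) to 0.14 ± 0.47; Krt19 was at 0.40 ± 0.59 (nuclear 1.67 ± 0.69, adjusted p = 0.197).

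Of AP-1 members 14 of 17 had a lower change in biliary cells (14 adjusted over the list alone), 4 under both scalings (median −1.78, 0.37 below all genes; camera adjusted p = 0.00433, adjusted p = 0.933 with an estimated correlation). Inflammation and chemokine genes lay 0.79 above all genes, although their median was −0.62 and 5 of 19 were lower (0 adjusted over the list alone; adjusted p = 0.0128, adjusted p = 0.933 with an estimated correlation). That list gave 0.0984 without untreated hepatocyte library 2 and 0.0863 without DDC hepatocyte library 3. The lymphocyte list (2 of 9 lower; adjusted p = 0.000742, adjusted p = 0.46 with an estimated correlation) and the mesothelial list (0 of 5; adjusted p = 0.0032, adjusted p = 0.398 with an estimated correlation) also lay above all genes. So did the neuronal control (3 of 12 lower; adjusted p = 0.0172, adjusted p = 0.556 with an estimated correlation), which gave 0.0665 without DDC hepatocyte library 1. None of these 3 passed under the nuclear scaling (adjusted p = 0.177, 0.0543 and 0.0812).

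As deposited 10156 genes passed (156 higher, 10000 lower, 1.5% higher), against 449 under the nuclear scaling (170 and 279, 37.9% higher) and 532 with edgeR (56% higher); both scalings gave 39 higher and 278 lower. Region calls were 19378 (12.9% higher), 1860 (23.5% higher) and 2444 (24.1% higher), with 325 higher and 1326 lower under both scalings. The median of all genes was −1.42 as deposited and −0.21 under the nuclear scaling, and deposited differences are to be read relative to −1.42. With only the compared groups in the fit, nuclear values called 168 genes (68 higher, 100 lower). Reads thinned to equal depth gave 2 genes (1 and 1) in that fit, so most of the genes named above did not pass there. Without DDC biliary library 1 or 3 region calls became 12240 or 12492. Hnf4a passed without untreated hepatocyte library 2 (−1.85, adjusted p = 0.00126), DDC hepatocyte library 3 (−1.52, adjusted p = 0.0442) or untreated biliary library 3 (−1.66, adjusted p = 0.0291), and Krt19 without untreated hepatocyte library 3 (1.07, adjusted p = 0.035).

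Placed on the axis from untreated hepatocytes (0) to untreated biliary cells (1), reprogrammed cells lay near the biliary end. Over 38166 biliary-higher regions DDC hepatocytes scored 0.589 ± 0.067, reprogrammed cells 1.022 ± 0.045 and DDC biliary cells 1.082 ± 0.013 (mean ± SD, n = 3). Over 1930 hepatocyte-higher regions the scores were −0.339 ± 0.116, 0.65 ± 0.244 and 0.916 ± 0.145. For the nuclear scaling the regions were chosen anew. There 16368 biliary-higher regions gave 0.497 ± 0.04, 0.913 ± 0.047 and 1.032 ± 0.016, and 8271 hepatocyte-higher regions gave 0.282 ± 0.044, 0.852 ± 0.14 and 0.998 ± 0.076. DDC hepatocytes thus scored −0.339 as deposited and 0.282 under the nuclear scaling in hepatocyte-higher regions. These scores come from unlike sets of regions, so scaling and choice of regions are not told apart. Reprogrammed cells differed from DDC hepatocytes by 0.433 and 0.989 as deposited. The exact two-sided permutation test of 3 against 3 libraries gave p = 0.1 for each, the smallest value it can give. Against DDC biliary cells it gave 0.1 for biliary-higher and 0.2 for hepatocyte-higher regions.

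**Figure D4:**
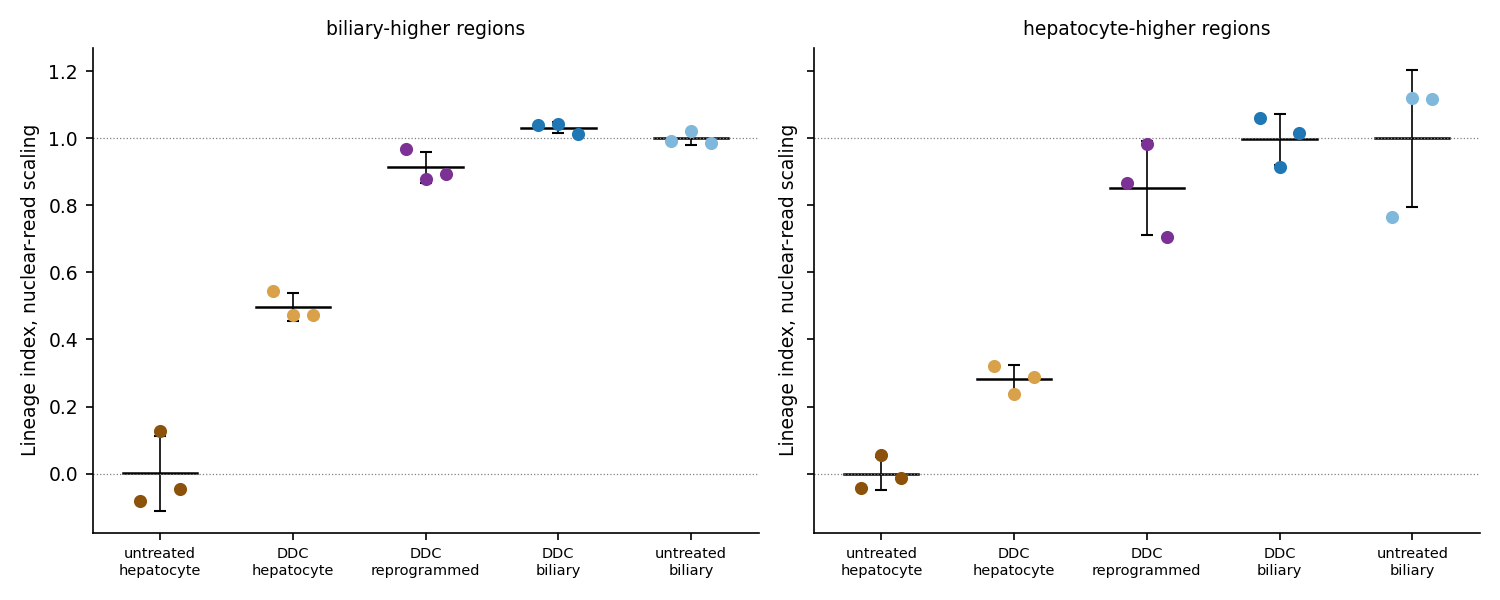
Lineage score of each library under the nuclear scaling. Reprogrammed cells scored 0.913 ± 0.047 in biliary-higher and 0.852 ± 0.14 in hepatocyte-higher regions, and DDC hepatocytes 0.497 ± 0.04 and 0.282 ± 0.044 (mean ± SD, n = 3). As deposited the last of these was −0.339 ± 0.116, over regions chosen on that scale.

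Regions that set untreated biliary cells apart were those that opened on reprogramming more often than others, in comparisons that share no library. Of 38982 biliary-higher regions 13906 rose in reprogrammed cells (35.7% against 26.4% of all; 10272 expected; odds ratio 3.18, nuclear 6.34). Of 1987 hepatocyte-higher regions 1386 fell (69.8% against 8.6%; 171 expected; odds ratio 31.5, nuclear 35). The changes of the comparisons correlated with r = 0.602 across regions (rho = 0.55; nuclear r = 0.618), and regions are not independent replicates. In both comparisons the hepatocyte libraries had a higher mitochondrial share and fewer nuclear reads. With no change the self-test moved the median of genes by 1.8 and 0.46 as deposited (nuclear 0.09 and 0.02). Whether part of the overlap stems from this was not tested. As deposited, regions that fell on reprogramming lay away from gene ends: 5.34% were within 1 kb of an end against 17.1% of all tested regions (ratio 0.312, 95% interval 0.28 to 0.347; 0.486, 0.452 to 0.521, within 2.5 kb). Those that rose did so at 15.1% (ratio 0.886, 0.856 to 0.916; 0.904, 0.879 to 0.929, within 2.5 kb). The intervals treat regions as independent. Low shares were not particular to reprogramming. The share was 4.78% in regions lower in untreated biliary cells than hepatocytes. It was 3.98% and 5.34% in those that rose and fell with DDC in biliary cells. It exceeded 17.1% in regions higher in untreated biliary cells (26.2%) or DDC hepatocytes (27.3%) than in untreated hepatocytes. It also did so in those lower for the difference of DDC effects (36.3%). The Abi3bp gene, of an extracellular matrix protein, held a distal example that fell (chromosome 16, 56598358 to 56598951; −3.12 ± 0.46).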

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

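The results below are those in which the effect of DDC differed between biliary cells and hepatocytes. The test of mitochondrial scaling was written after the result had been seen; the tests with thinned reads and with other splits were written before, and the fit without thinning that goes with the former was added after. As deposited 19378 regions and 10156 genes differed, and under the nuclear scaling 1860 and 449. The change was higher in biliary cells at Lce1m (3.68), Tmem200a (3.34), Fam124b (3.24) and Il23a (2.94), and all 4 passed under both scalings. It was lower in biliary cells at Arl1 (−4.24), Lcn12 (−4.17) and Pde6c (−4.05), of which Pde6c passed under both scalings while Arl1 (nuclear adjusted p = 0.0577) and Lcn12 (0.0553) did not. Hes1 (−2.25), Ccn1 (−2.71), Atf3 (−3.25), Fosb (−2.95) and Scd1 (−3.19) passed under both, and Alb (−2.01), Sox9 (−1.66) and Spp1 (−2.34) as deposited only. These calls come from the fit of all libraries. With reads thinned to equal depth and only the compared groups in the fit, 2 genes passed (1 higher, 1 lower), so most of these calls were not kept. The lists were AP-1 (adjusted p = 0.00433), inflammation (0.0128), lymphocyte (0.000742), mesothelial (0.0032) and neuronal control (0.0172). With an estimated correlation none passed (0.933, 0.933, 0.46, 0.398 and 0.556). The last 3 did not pass under the nuclear scaling (0.177, 0.0543 and 0.0812).

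Whether any split of the libraries would do as well was tested by calling genes and regions under other splits of the same libraries. For the difference of the DDC effects 2 of 100 splits, the real grouping included, reached the real 19378 regions. The other of these splits gave more calls (20678). The share of such splits lay under the 0.05 set beforehand. Splits that mix DDC and untreated hepatocytes also mix their mitochondrial shares and depths. In the self-test with no change these alone called 11824 of 15997 genes for this difference as deposited. The low share can therefore stem from the scaling, and no conclusion on a DDC effect is drawn from it. For genes 12 of 100 splits reached the real 10156 (highest other 11946), so chance was not excluded. The other comparisons have 10 splits each, and only 1 split, the real grouping, reached its own count; these splits are too few for a share under 0.05. The real counts and the highest others were 40969 and 0 regions and 13902 and 0 genes for untreated biliary cells against hepatocytes, and 33777 and 5064 regions and 13553 and 5684 genes for DDC in hepatocytes. For DDC in biliary cells they were 8721 and 0 regions and 498 and 0 genes, for reprogrammed cells against DDC hepatocytes 24657 and 0 and 3952 and 0, and against DDC biliary cells 440 and 0 and 4 and 0.

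Calls between DDC and untreated hepatocytes lay almost all in the higher direction, and these libraries enter the difference above. The median change of regions was 1.01 as deposited and 0.32 under the nuclear scaling, so most of the shift may stem from mitochondrial reads in the scaling. In the self-test with no change between groups, the median of genes was 1.49 as deposited, against 1.54 in the data. Mitochondrial share and depth alone can thus give a shift of about this size in genes. A global opening of chromatin and a change of scale cannot be told apart here, because all values are shares of a fixed total. A fit of only these groups on nuclear reads thinned to equal depth had 0 region calls, against 33777 as deposited with all libraries. The same fit without thinning had 0 as well. Its median change was 0.28 in regions and 0.2 in genes, against 0 and 0.11 with thinning. With no region calls left, the share of higher calls that was to decide could not be computed. A role of the few nuclear reads in untreated hepatocytes therefore cannot be told apart from a true change either.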

How the results depend on the processing

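Settings planned before the data were examined were other pseudocounts, filters, scalings, fits, gene assignments and correlations, the replicate block and each library left out; nuclear scaling, edgeR, thinning, its counterpart without thinning and the fit without untreated hepatocytes were chosen after seeing the data. Over all settings 230 comparison results stayed within 1.5-fold of their value and 111 moved further. Of results on named genes 2485 stayed as they were, called or not, 172 lost a call, 66 gained 1 and 20 turned in sign. Of those on lists 712 kept their call and 68 lost it. Of those on named regions 560 kept it and 70 lost it. Calls that involve untreated hepatocytes depended on the scaling and on the groups in the fit. Those between reprogrammed and biliary cells moved with the scaling, the test, the pseudocount, the groups in the fit and any library left out, but not with the filter or the replicate block. The cause was not tested beyond the self-test. Removing the filter moved none of 12 results. The motif alternatives (window and background) were not run.

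Below, counts are regions then genes. Quantile normalization gave 23820 and 5913 for untreated biliary cells against hepatocytes, 5891 and 1915 for DDC in hepatocytes, 982 genes for DDC in biliary cells, 1052 and 32 for reprogrammed against biliary cells and 5248 and 726 for the difference of DDC effects; the lineage difference was 0.501 in biliary-higher and 0.676 in hepatocyte-higher regions. Median centring gave, in the same order, 6094 genes; 10286 and 2362; 995 genes; 747 and 17; 9955 and 966; and 0.642 in hepatocyte-higher regions. Nuclear scaling gave 26102 and 6343; 9598 and 2200; 2741 regions; 0 regions for reprogrammed against biliary cells; 1860 and 449; 11232 and 2318 for reprogrammed cells against DDC hepatocytes; and 0.57. Of 154 named genes it left 134 as they were, called or not, and of 35 list calls it kept 28.

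With edgeR the counts were 19370 and 4773, 2985 and 814, 2603 genes, 2113 and 478, and 2444 and 532. Nuclear values with only the compared groups in the fit gave, in the same order, 12571 and 2750; 0 (9519 at unadjusted p under 0.05) and 1; 16833 and 4473; 5711 and 1182; and 274 and 168. Thinned reads in that fit gave 1817 and 829; 0 and 0; 14298 and 4068; 5039 and 1133; and 0 (6901 at unadjusted p under 0.05) and 2. Beside the fit without thinning, depth thus took most calls between untreated groups and for the difference of DDC effects, and a smaller share where untreated hepatocytes were absent; for DDC in hepatocytes almost none were left to lose. With thinned reads of all libraries the lineage difference was 0.474 in hepatocyte-higher regions. A pseudocount of 0.1 gave 1445 and 70 for DDC in biliary cells, 12422 and 2168 for reprogrammed cells against DDC hepatocytes, 0 and 0 against DDC biliary cells (2501 and 402 at unadjusted p under 0.05) and 0.738 in hepatocyte-higher regions. With only the compared groups in the fit the counts were 21323 regions for DDC in hepatocytes, 17311 and 4160 for DDC in biliary cells, 7574 genes for reprogrammed cells against DDC hepatocytes and 6217 and 1084 against DDC biliary cells. Without untreated hepatocytes in the fit the last 3 became 13659 and 2522, 9270 genes, and 1968 and 271. Regions within 1 kb of a gene end gave 95 genes for DDC in biliary cells and 2442 for reprogrammed cells against DDC hepatocytes.

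With an estimated correlation 0 of the 35 list calls remained, while nuclear scaling kept 28, quantile normalization 33 and regions within 1 kb of a gene end 23 of 30 tested. Counting lists that newly passed, other settings called 30 to 45. Within 2.5 kb of a gene end the ratio for regions that fell was 0.486 in place of 0.312.

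In sign, Hnf4a turned to 1.58 between untreated groups with regions within 1 kb of a gene end. For DDC in hepatocytes Alb turned to −0.02 (quantile), −0.01 (nuclear, also with only the compared groups), −0.04 (edgeR) and −0.01 (thinned), Hnf4a to −0.04 (nuclear, likewise) and −0.12 (edgeR), Spp1 to −0.39 (thinned) and Epcam to −0.42 (median), −0.50 (quantile), −0.40 (nuclear, likewise), −0.33 (edgeR) and −1.19 (thinned). Alas1, the first enzyme of heme synthesis, turned from −1.79 to 0.36 in reprogrammed cells with regions within 1 kb. Epcam turned to 1.16 (median), 1.27 (quantile) and 1.12 (nuclear) for the difference of DDC effects.

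With each library left out the counts ranged from 4431 to 7542 regions and 101 to 314 genes for DDC in biliary cells, 15481 to 21411 and 2022 to 3326 for reprogrammed cells against DDC hepatocytes, 0 to 53 and 0 to 0 against DDC biliary cells (403 to 584 genes at unadjusted p under 0.05), and 12240 to 28931 regions for the difference of DDC effects. The lineage differences stayed within 0.371 to 0.465 and 0.844 to 1.122.

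The samples were not treated as paired, since no label marks pairs and correlations of libraries with the same number were −0.15 to 0.22 (0.02 to 0.22 among DDC groups), not all over 0.1. Each DDC library did correlate best with its own number in the other DDC groups, which untreated libraries did not; this hint from the data leaves shared animals among the DDC groups open. The replicate block, set within treatment for groups of the same treatment, left all 13 results within 1.5-fold: 41773 and 13972 (untreated groups), 33882 and 13570 (DDC in hepatocytes), 8751 and 502 (DDC in biliary cells), 25883 and 4255 and 436 and 4 (reprogrammed cells against DDC hepatocytes and biliary cells), 20749 and 10476 (difference of DDC effects) and 37 lists.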

Other observations

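The DDC effects in hepatocytes and in biliary cells were weakly correlated across genes. Across 16230 genes, which are not independent replicates, the DDC effects correlated with r = 0.18 under the nuclear scaling (rho = 0.21) and r = 0.07 as deposited (rho = 0.13), in comparisons that share no library. Under the nuclear scaling 83 genes rose in both cell types, more than the 35.1 expected from the totals of 1563 and 364. That expectation takes every gene as equally likely to be called. The 1563 come from the fit of all libraries. With only the compared groups in the fit, nuclear values called 0 genes as higher for DDC in hepatocytes. As deposited 308 rose in both, fewer than the 396 expected. In the fit of all libraries Ccl2 rose in both (1.24 ± 0.31 in hepatocytes and 2.81 ± 0.31 in biliary cells under the nuclear scaling).

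None of the further lists passed the camera test between reprogrammed cells and DDC hepatocytes. Fetal liver progenitor genes had 4 that rose and 1 that fell of 13 (5 and 1 adjusted over the list alone; camera adjusted p = 0.741). Cell cycle genes had 3 of 21 that rose (adjusted p = 0.889), and Ccnd1, which encodes cyclin D1, rose by 1.56 ± 0.33 (adjusted p = 0.0021). Wnt targets had 2 that rose and 1 that fell of 17 (adjusted p = 0.231), interferon response 3 of 13 that rose (adjusted p = 0.915) and NRF2 targets 1 of 16 (adjusted p = 0.231). Heme synthesis had 1 that rose and 2 that fell of 14 (adjusted p = 0.199), among them Alas1 (−1.79 ± 0.42, adjusted p = 0.00403), which turned to 0.36 with regions within 1 kb of a gene end (adjusted p = 0.621). Lymphocyte genes had 4 of 9 that rose (adjusted p = 0.915), endothelial 3 that rose and 1 that fell of 15 (adjusted p = 0.682), erythroid 2 and 1 of 6 (adjusted p = 0.563) and the neuronal control 7 of 12 that rose (median 1.1; 1 under both scalings; adjusted p = 0.125).

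The explanations tested below were chosen before the results were seen, and the placing of left-out hepatocyte and biliary libraries was added after. Reprogrammed libraries lay between hepatocyte and biliary libraries, which a mixture of hepatocytes and biliary cells could also give. Under a mixture of the DDC hepatocyte and DDC biliary profiles, biliary-higher and hepatocyte-higher regions must imply the same biliary share. They implied 84.1% and 89.5% in library 1, 79.2% and 97.9% in library 2 and 65.2% and 74.5% in library 3. The mean difference was −11.2 points (−5.41, −18.8 and −9.27, with ranges of −6.89 to −3.54, −20.5 to −16.2 and −10.7 to −7.52 over left-out libraries). Hepatocyte and biliary libraries of DDC mice, each placed on the axis of the others, gave differences of −4.32 to 5.8 points, so the mean lay beyond the spread between libraries while library 1 alone did not exceed it in size. As a set this argues against a mixture of only these measured profiles, and it leaves open admixture of other cells or cell states and differences in library quality.

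Depth was the other explanation tested for reprogrammed cells, as DDC hepatocytes had fewer nuclear reads. After thinning to 1191409 reads per library the biliary list lay 3.05 above the hepatocyte function list in median change, against 3.07 before. The separation of these lists is thus not in line with an effect of depth alone.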
